A study of Mus musculus with 6 samples.

How the data were processed

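The study profiled 6 libraries of mouse embryonic stem cells: input DNA, p53 ChIP and p53S18P ChIP, each from untreated cells and from cells given 0.5 µM adriamycin for 8 hours. Per the labels' protocols, chromatin immunoprecipitation followed an Agilent protocol for mammalian cells and libraries followed Illumina's ChIP-seq protocol. The antibodies were from Santa Cruz (p53) and Cell Signaling (p53S18P). The deposited files are lists of aligned reads, 1 line per read, with chromosome, first position, last position and strand. They hold no count, signal or peak made by the authors. Reads were aligned to mm9, per the submitters' processing notes. The aligner and its filters are not given in the sources used here. Every read spans 35 bases. At the ends of the mitochondrial chromosome the reads overhang by 3 bp on each side when positions are counted from 1 with both ends included, and positions were read in that way.

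Mitochondrial reads were left out of site calling and comparisons. On the nuclear chromosomes 1 read was kept per position and strand, which retained between 96.5% and 99.4% of reads: 9111682 and 16603512 for p53 (untreated and treated), 13889465 and 8773552 for p53S18P, and 16824456 and 19276963 for the inputs. Fragment length was the lag between 50 and 400 bp with the highest count of opposite-strand pairs on autosomes: 97 and 110 bp for p53, 109 and 85 bp for p53S18P, 115 and 110 bp for the inputs. The 5′ ends were moved by 50% of that length towards the fragment's middle.

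Sites were called by a Poisson upper-tail test in windows of 200 bp with a step of 50 bp. The expected count was the largest of the input in the window, the input in 1, 5 and 10 kb around it, each scaled by total retained reads, and the genome mean over 2424 Mb of 1 kb bins that held an input read. Windows with a Benjamini-Hochberg q of at most 0.01, over all windows holding a read, were merged within 200 bp. A site needed at least 2-fold over the expected count and reads on both strands. Each ChIP library was tested over the input of its own condition, which the study's design text names as the control. Sites of the 4 libraries that overlapped were merged. Sites of different libraries were matched by summits within 250 bp, and chance matches were counted after 100 random moves of one list along the chromosomes. Enrichment was log2 of reads over scaled input reads, with 1 read added to each.

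Treated and untreated libraries were compared at the 89012 merged sites by a two-sided exact binomial test, with the ratio of reads outside sites as the expected odds (1.57 for p53 and 0.509 for p53S18P) and Benjamini-Hochberg adjustment over sites. A site was called higher or lower at an adjusted p of at most 0.05 and a fold of at least 2, with 0.5 reads added to each count for log2 values. A library with 0 reads at a site was given 3 reads to state a fold. That fold leaves out the counting error of the other library, so exact 95% limits are given beside it. The difference between antibodies in the response to treatment was a Wald test on the log ratio of 4 counts. Libraries without sites, drawn from the summed inputs smoothed over 1 kb, gave the overlap and correlation that shared inputs produce when the background follows the inputs. Exact intervals are Clopper-Pearson at 95%. Sequenced reads without molecular identifiers are not independent molecules, so intervals on reads cover counting error alone. Intervals on shares of sites take each called site as 1 independent trial and leave out the error in calling sites.

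The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. Site calling was tested on simulated data, with 250 sites of each size added to a library drawn from the inputs. Over 33141372 windows at the depth of the treated p53 library, it recovered 37.6% of sites 8-fold over the genome mean, 95.2% at 16-fold and 100% at 32-fold, and called 39 sites elsewhere. At the depth of the treated p53S18P library, over 23348284 windows, it recovered 6.8%, 70% and 100%, and called 16 elsewhere. For untreated p53, over 23921126 windows, the shares were 7.6%, 67.2% and 99.6% with 18 elsewhere, and for untreated p53S18P, over 30440193 windows, 23.6%, 92.4% and 100% with 22 elsewhere. Sites 4-fold over the genome mean were nearly all missed: 1.2% were recovered for treated p53, 0% for treated p53S18P and 0.4% for each untreated library. The treatment comparison was simulated over 89012 sites with 50 changed per size. Changes were placed only at sites with a mean of at least 20 reads, on the scale of the untreated library. Most of the 89012 sites hold fewer, so the shares recovered do not hold for them. A 4-fold rise was recovered at 96% of sites for p53 and 78% for p53S18P, and a 4-fold fall at 98% and 68%. A 2-fold rise was recovered at 16% with either antibody, and a 2-fold fall at 42% for p53 and 14% for p53S18P. The 2-fold limit on the fold holds back many true 2-fold changes. Among unchanged sites 3 were called for p53 and 1 for p53S18P. For the difference between antibodies, placed at sites with such a mean for both antibodies, a 4-fold difference was recovered at 54% of sites. A 2-fold one was recovered at 14%, with 0 calls among unchanged sites.

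The following choices were made before the data were examined: the tests, the thresholds, most of the alternatives, and the rule for the sites named. That rule took the 15 sites with the smallest p in the treated p53 library that were also called with p53S18P in treated cells, and in each treatment comparison the 3 sites with the largest fold in each direction among those past the threshold, all with at least 20 reads in a library compared. Gene lists, named target genes and a motif search were also fixed then and were not run, since no annotation or sequence of mm9 was used here and positions were not converted between builds. The gene table at hand was of another build and was not used. Alternatives fixed then changed the treatment of duplicate positions, the input, the scaling, the q and fold thresholds, the depth, the fragment length, the interval counted and the overlap that counts as shared. A background measured in each 100 kb and counts of plus strand reads were added after seeing the data.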

Results

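Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map binding of p53 in mouse embryonic stem cells of a 129X1 x 129S1 background. The p53 protein is a transcription factor that is stabilised and modified after DNA damage. Cells were left untreated or received 0.5 µM adriamycin for 8 hours. Adriamycin, also known as doxorubicin, is a topoisomerase II poison that breaks DNA. From each condition 3 libraries were analysed: an immunoprecipitate with an antibody to p53, an immunoprecipitate with an antibody labelled anti-p53S18P, and input DNA that was not immunoprecipitated. The name p53S18P is used for p53 phosphorylated on a serine of its amino-terminal transactivation domain. The 6 groups thus held 1 library each. The p53 antibody gave 9177279 aligned reads from untreated and 16929476 from treated cells, and the p53S18P antibody gave 14122942 and 8831858. The inputs held 17448399 and 19551648 reads. With 1 library per group no difference has a replicate check. Each p-value and 95% interval compares libraries, not conditions. Those on reads cover counting error alone. Exact intervals on shares of sites take each called site as 1 independent trial and leave out the error in calling sites. Positions refer to mm9. No gene annotation of that build was used here, so sites are given by position and no site is assigned to a gene.

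The first question was where each antibody found more reads than the input. Sites were found with both antibodies in both conditions, and far more after adriamycin. The p53 antibody gave 16629 sites in untreated and 78339 sites in treated cells. The p53S18P antibody gave 8454 and 56940 sites. In the opposite direction, with the input tested over the ChIP library, the same procedure called 112 and 56 sites for the p53 antibody and 344 and 215 sites for the p53S18P antibody. The treated sites included most of the untreated ones: 15764 of the 16629 untreated p53 sites (94.8%, exact 95% interval 94.4% to 95.1%) and 7873 of the 8454 untreated p53S18P sites (93.1%, 92.6% to 93.7%) had a treated summit within 250 bp. Site lists moved at random along the chromosomes gave 263 and 97.9 such matches on average. Median site width was 350 bp in each of the 4 libraries.

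Merging the 4 lists gave 89012 sites. The largest classes were 31366 sites called with the p53 antibody in treated cells alone, 30591 called with both antibodies in treated cells, and 9754 called with the p53S18P antibody in treated cells alone. A further 8026 sites were called with the p53 antibody in both conditions and with the p53S18P antibody after treatment, and 7486 were called in all 4 libraries. Median read density in the last class, per 10000000 retained reads, was 43.9 untreated and 103.0 treated with the p53 antibody, 20.2 and 110.6 with the p53S18P antibody, and 4.75 and 5.19 in the inputs. Over all merged sites, the share of reads inside sites was 9.98% untreated and 22.4% treated for p53, 4.77% and 23.2% for p53S18P, and 2.73% and 2.22% for the inputs. Counts of sites rest on the threshold and on depth. At a q of 1e-05 in place of 0.01 they were 10916 and 47687 for p53 and 5545 and 34331 for p53S18P.

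**Figure D1:**
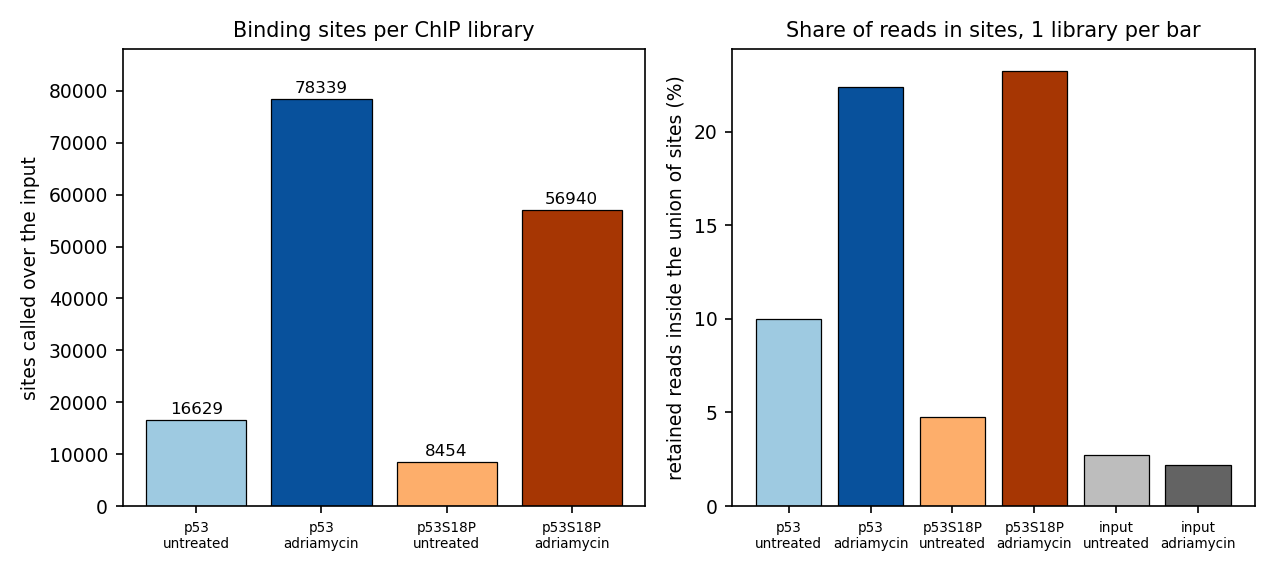
The left bars give the number of sites called in each of the 4 ChIP libraries over the input of the same condition, from 8454 to 78339. The right bars give the percentage of each library's retained reads inside the 89012 merged sites, which was 22.4% and 23.2% in the treated ChIP libraries and 2.73% and 2.22% in the inputs, with 1 library per bar.

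The second question was how binding seen with the p53 antibody differed between treated and untreated cells. Relative to reads outside sites, 38652 of the 89012 sites (43.4%) were higher in the treated library by at least 2-fold at an adjusted p of at most 0.05 (exact binomial test, Benjamini-Hochberg), and 176 (0.198%) were lower. The median log2 fold change was 1.50, with quartiles of 0.93 and 2.14, and 2.01 when input-corrected. Sites called only because of a high treated count would favour that direction, so the 16406 merged sites called in the untreated library were also taken alone. Of these, 11257 (68.6%) were higher and 161 lower after treatment, with a median of 2.58-fold. The 62342 sites called after treatment and not before had a median of 3.18-fold.

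Among sites past the threshold with at least 20 reads, the largest p53 differences were at 1:192040751-192041200, 8:96897101-96897600 and 9:68228451-68229100. These went from 0 untreated reads to 73, 62 and 62 treated reads. When 0 is replaced by 3 reads they were 15.5-fold, 13.2-fold and 13.2-fold higher (lower exact 95% limits 12.3, 10.4 and 10.4). Only 1 lowered site had as many reads: 17:66823651-66823950 went from 21 to 13 reads, or 0.394-fold (95% interval 0.181 to 0.825, adjusted p = 0.0289, exact binomial test). That call ended when 500 bp around the summit or plus strand reads were counted. Scaling by total reads gave 30056 higher and 224 lower sites. Lowered sites numbered 116 with 500 bp around the summit and 72 after thinning, of which 92 and 51 were among the 176. Setting the median site to no change shifts every log2 value down by 1.50 and so balances the directions by construction: 874 sites were then higher and 1639 lower, 34.8% in place of 99.5% of the calls being higher.

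The third comparison repeated this with the p53S18P antibody, where the difference between conditions was larger. With it, 57679 of the 89012 sites (64.8%) were higher after adriamycin and 83 (0.0932%) lower, with a median log2 fold change of 2.56, quartiles of 1.71 and 3.30, and a median of 3.62 when input-corrected. Of the 8395 merged sites called in the untreated p53S18P library, 7704 (91.8%) were higher and 81 lower, with a median of 5.61-fold. The 48422 sites called after treatment and not before had a median of 7.46-fold. The 3 largest differences were at 17:56335301-56335750, 1:127412501-127412900 and 5:140716851-140717300, which went from 0 to 58, 56 and 50 reads. With 3 reads in place of 0 they were 38.0-fold, 36.7-fold and 32.7-fold higher (lower exact 95% limits 29.9, 28.8 and 25.6).

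The 3 largest losses of p53S18P signal were at 3:96042151-96042400, 13:23775051-23775400 and 13:23663601-23664150. At the first, reads went from 21 to 0, 3.56-fold lower with 3 reads in place of 0 (upper exact 95% limit of the ratio 0.377). At the second they went from 20 to 0, 3.39-fold lower in the same way (upper limit 0.398). At the third they went from 43 to 1 read. The last is a ratio of 0.0457 (95% interval 0.00113 to 0.268, adjusted p = 2.74e-06, exact binomial test). The p53 antibody had 4 and 4 reads, 1 and 4 reads, and 1 and 9 reads at these positions, and no p53 site was called there. With 500 bp around the summit counted, the log2 fold change was -1.45 at 3:96042151 and -2.93 at 13:23775051. With the median site set to no change, a shift of 2.56 on the log2 scale that balances the directions by construction, 1421 sites were higher and 1410 lower, so that 50.2% in place of 99.9% of the calls were higher. Scaling by total reads gave 50714 higher and 244 lowered sites. Adjusting p over only those merged sites that were called with this antibody gave 135 lowered sites.

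Lowered p53S18P sites lay close together on chromosome 13, a region singled out after its values were seen. Of the 83 lowered sites, 56 were also lower with background per 100 kb, 58 with 500 bp around the summit, 50 after thinning and 14 with plus strand reads, which hold fewer counts. Of the 83, 18 lay within 13:21000001-24000000, between 21827251 and 23853900. Their log2 fold changes ran from -4.38 to -1.17, and 17 of the 18 were called in the untreated p53S18P library alone. Of the other 62 p53S18P sites of the region, 46 were higher after treatment and 12 had a negative log2 fold change. All 28 sites of the region called in the untreated p53S18P library alone had a negative value, which being called there alone favours. With the p53 antibody the 18 lowered sites together held 61 untreated and 128 treated reads, a ratio of 1.34 (exact 95% interval 0.977 to 1.84). Read density at these sites, relative to the genome mean, was 2.56 untreated and 2.94 treated with p53, against 2.61 and 2.08 in the inputs. With p53S18P it was 13.96 and 2.35. The p53 reads thus lay near the input level, and their ratio says little about p53 binding there.

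**Figure D2:**
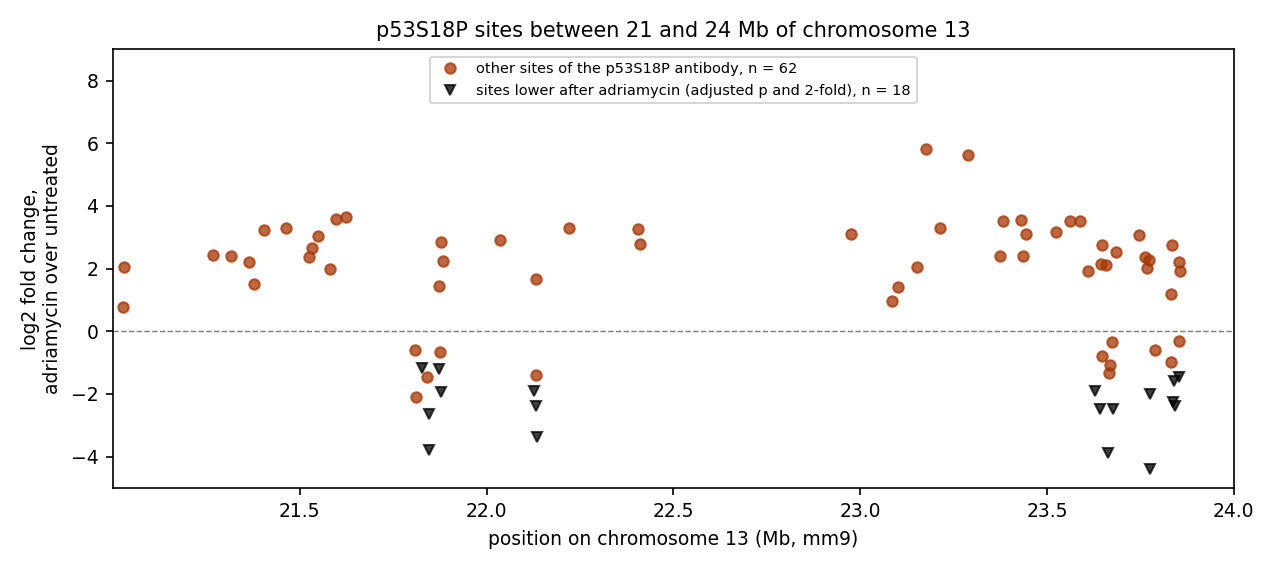
Each point is 1 of the 80 p53S18P sites between 21 and 24 Mb of chromosome 13, by position (Mb, mm9) and log2 fold change of treated over untreated p53S18P reads with 0.5 reads added. The 18 triangles are sites lower after adriamycin, from -4.38 to -1.17, and the 62 circles are the other sites.

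The 15 sites with the smallest p in the treated p53 library, among those also called with the p53S18P antibody, were called in all 4 libraries. They held between 458 and 1554 treated p53 reads, 70.8 to 182 times the expected number, and between 61 and 410 untreated ones. All 15 were at least 2-fold higher after adriamycin with the p53S18P antibody, from 2.41-fold to 38.1-fold with a median of 5.09-fold when 0.5 reads were added to each count. With the p53 antibody 4 of the 15 were, and the median was 1.47-fold. The p53 log2 value of 3:52406851 was 0.97 and passed 2-fold with all reads kept (1.05), input correction (1.03), thinning (1.03) and plus strand reads (1.12). The p53S18P log2 values of 10:90880651 (0.955) and 5:22725051 (0.960) fell under 2-fold with scaling by total reads, and those of 12:111962801 (0.983), 8:13139501 (0.991) and 17:56847801 (0.829) with background per 100 kb. With the median site set to no change, p53S18P increases of at least 2-fold were left at 11:78470701, 7:105707901 and 10:117481751 alone. The site at 11:78470701-78473650 stood highest: it rose from 61 to 1554 p53 reads, 16.2-fold (95% interval 12.6 to 21.3, adjusted p = 2.16e-241, exact binomial test), and from 46 to 902 p53S18P reads, 38.5-fold (28.6 to 52.98). The inputs held 13 and 25 reads there. The other p53 increases of at least 2-fold were at 7:105707901-105709700 (3.78-fold), 13:55973751-55974700 (3.50-fold) and 15:73076351-73077700 (2.80-fold).

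By contrast, 3:61166751-61168650, first in the list, went from 300 to 751 p53 reads, 1.59-fold (1.39 to 1.83), and from 137 to 600 p53S18P reads, 8.60-fold (7.13 to 10.4). At 8:13139501-13140500 the p53 ratio was 0.994 (0.869 to 1.14), with 356 and 556 reads in libraries of different depth, while the p53S18P ratio was 3.02 (2.56 to 3.55). Low p53 ratios at strong sites depended in part on keeping 1 read per position and strand. With all reads kept, the p53 log2 value rose at every strong site, for example from 0.195 to 0.334 at 12:111962801 and from 0.533 to 0.680 at 10:117481751. The median over all sites stayed at 1.495. The remaining 9 strong sites lie at 3:104257601-104259100, 12:111962801-111964050, 10:90880651-90882000, 10:117481751-117483050, 17:56847801-56850400, 5:22725051-22726300, 3:52406851-52408000, 4:48834501-48835800 and 7:139920601-139921900. With the median site set to no change, 11:78470701-78473650 was the only strong site still higher past the threshold with the p53 antibody.

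**Figure D3:**
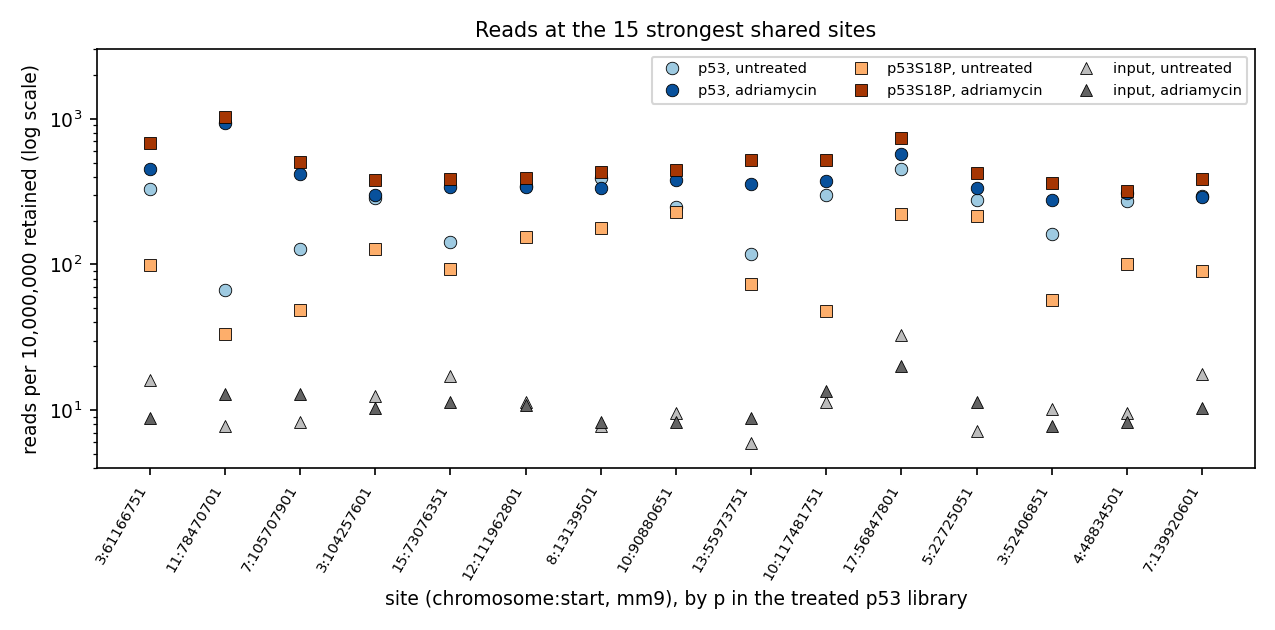
Each column is 1 of the 15 strongest sites, named by chromosome and start, and the vertical log axis gives reads per 10000000 retained reads in the 6 libraries. Treated p53S18P values lie above untreated ones at each site, whereas treated and untreated p53 values differ most at 11:78470701, where they are 935.9 and 66.9.

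The p53S18P ratio exceeded the p53 ratio in each band of the list. In the 1000 strongest merged sites of the treated p53 library the median ratio of treated to untreated reads was 1.72 with the p53 antibody and 5.27 with the p53S18P antibody. At ranks 1001 to 5000 the medians were 2.64 and 7.02, at ranks 5001 to 20000 they were 3.45 and 7.64, and at ranks 20001 to 78187 they were 2.93 and 4.58. Of the 1000 strongest sites, 99.4% were already called in untreated cells with the p53 antibody and 95.6% with the p53S18P antibody. In the weakest band these shares were 3.85% and 0.469%.

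**Figure D4:**
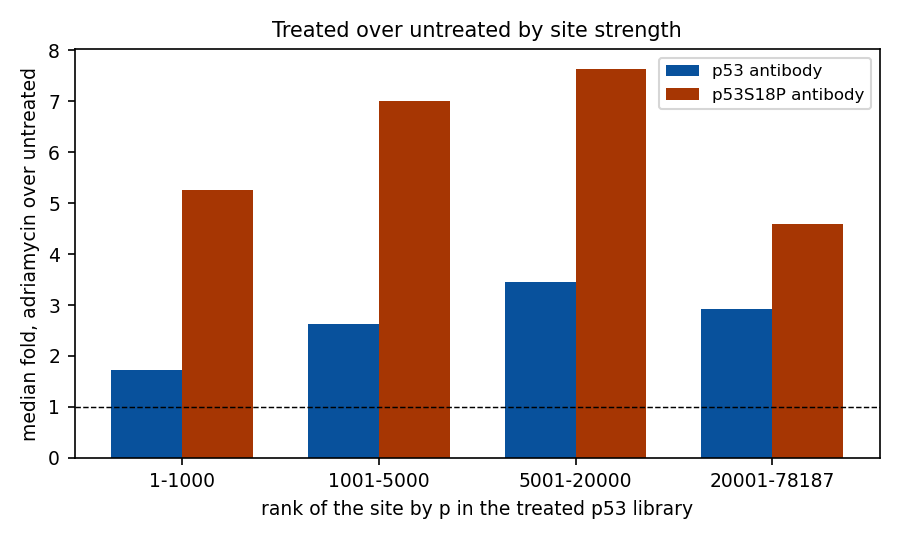
Bars give the median ratio of treated to untreated reads, relative to reads outside sites, in 4 bands of sites ranked by p in the treated p53 library, for the p53 antibody and the p53S18P antibody. The p53 median is 1.72 in the strongest band and 3.45 at ranks 5001 to 20000, and the dashed line marks a ratio of 1. The ranking uses the reads that are also the numerator of the p53 ratio.

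The fourth comparison set the antibodies side by side within a condition. In treated cells 46007 of the 78339 p53 sites (58.7%, exact 95% interval 58.4% to 59.1%) had a p53S18P summit within 250 bp, and 46006 of the 56940 p53S18P sites (80.8%, 80.5% to 81.1%) had a p53 summit. In untreated cells these were 7515 of 16629 (45.2%, 44.4% to 46.0%) and 7515 of 8454 (88.9%, 88.2% to 89.6%). Lists moved at random matched 909.9 and 28.0 times on average in 100 moves, with highest values of 1018 and 46. The antibodies shared the input of their condition. Libraries simulated without sites against those inputs gave 12 and 3 sites with 2 shared in treated cells, and 4 and 4 sites with 1 shared in untreated cells. They were drawn from the inputs and hold no background that departs from them. Outside sites, log2 reads per 100 kb relative to the untreated input had standard deviations from 0.14 to 0.32 in the ChIP libraries. The simulation cannot tell how many shared calls such background gives.

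Across 88037 sites called with either antibody in treated cells, log2 enrichment over the input had a Pearson correlation of 0.64 and a Spearman correlation of 0.64 between antibodies. Sites are not independent replicates, and the shared input alone gave a Pearson correlation of 0.38 in the simulation. The covariance was 0.73 against a simulated 0.28. In untreated cells, over 17301 sites, the correlations were 0.62 and 0.66, and the covariance was 0.68 against a simulated 0.28. Part of each excess may come from the shared inputs.

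Whether the antibodies responded differently to adriamycin was tested per site on the ratio of the 4 counts (Wald test, Benjamini-Hochberg over sites). The log2 fold change was larger with the p53S18P antibody at 8946 of the 89012 sites (10.1%) and smaller at 6. The median difference was 1.00 on the log2 scale. At the 5706 sites with at least 100 reads for each antibody the median log2 fold changes were 1.27 with p53 and 2.73 with p53S18P, and the median difference was 1.47. There the fold changes of the antibodies had a Pearson correlation of 0.61 and a Spearman correlation of 0.59 across sites, against 0.03 and 0.06 over all sites, most of which hold few reads. Sites higher after treatment with both antibodies numbered 31467, where independent lists of these lengths would share 25046. Sites with more reads pass the threshold more readily with either antibody, so nothing is drawn from that excess. Sites lower with both numbered 2. After the median difference was taken out, 775 sites (0.871%) still differed, 731 of them with a larger p53S18P value.

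The inputs showed how even the controls were. Per autosome, the treated over untreated input ratio of retained reads lay between 0.964 on chromosome 11 (95% interval 0.962 to 0.967) and 1.03 on chromosome 12. In 2375 autosomal bins of 1 Mb the log2 ratio had a standard deviation of 0.12, against 0.02 expected from counting, and a range from -0.52 to 0.38. Treated p53 sites were densest on chromosome 11, with 47.9 per covered Mb, and among autosomes sparsest on chromosome 3, with 25.7. Chromosome X had 10.8 per covered Mb, with input coverage of 0.421 and 0.433 of the autosomal mean. The Mb with the most treated p53 sites was 11:117000001-118000000, with 146 treated and 34 untreated p53 sites and 98 treated and 14 untreated p53S18P sites. The log2 ratio of treated to untreated input was -0.32 there and between -0.36 and -0.26 in the 5 densest Mb. A lower treated input favours treated calls. Untreated calls do not use the treated input, and chromosome 11 was densest for them too. It had 9.82 untreated p53 sites and 4.61 untreated p53S18P sites per covered Mb.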

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

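Chosen only after results were seen were the test of chance placement, the test for p53S18P reads at sites without a p53S18P call (medians of this enrichment by site strength were known) and, for the single factor, the 2 shares at sites with at least 100 reads. The test for fragments read from both ends was set out after a count of plus strand reads, which cannot bear on it, had been seen. The difference between antibodies in the response to adriamycin was tested per site, and it was larger with the p53S18P antibody at 8946 sites and smaller at 6 (Wald test, Benjamini-Hochberg). Of the sites named by the rule, 16 differed. On the log2 scale, p53S18P minus p53, the difference was 2.43 at 3:61166751, 1.24 at 11:78470701, 1.75 at 7:105707901, 1.59 at 3:104257601, 0.87 at 15:73076351, 1.46 at 12:111962801, 1.60 at 8:13139501, 1.33 at 13:55973751, 3.20 at 10:117481751, 1.49 at 17:56847801, 0.79 at 5:22725051, 2.01 at 3:52406851, 1.58 at 4:48834501, 2.21 at 7:139920601 and 7.85 at 1:127412501, where the untreated p53S18P library held 0 reads and the value depends on the 0.5 reads added. At 13:23663601 it was -5.90, with 1 read in the treated p53S18P library.

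The larger p53S18P response had a median of 1.00 on the log2 scale. At sites with at least 100 reads per antibody it was 1.47, and 1.70 with input reads taken off. Uneven background along the chromosomes is argued against as its whole source: with reads outside sites compared in each 100 kb the median difference was 0.79, above the 0.4 set as the limit. A single factor for all sites, such as a weaker pull-down in the untreated p53S18P library, stays open and may account for the shift of the median. After the median was taken out 0.871% of sites differed. This met the bound of 5% set before the value was seen, and taken alone it fits a single factor. In simulated data, however, only 14% of 2-fold differences passed, against 54% of 4-fold ones. Those differences were placed at sites with a mean of at least 20 reads for both antibodies. Most sites hold fewer, so recovery over all sites was not measured. The explanation was therefore left open after 2 further shares were computed. At the 5706 sites with at least 100 reads per antibody the share was 9.01% (298 larger and 216 smaller), and with input reads taken off it was 4.72% of 5337 sites. The standard deviation of the difference there was 0.62 against a median counting error of 0.36, and 0.74 against 0.45 with input reads taken off, which goes against a single factor if counting is the only error. The error between libraries is unknown, so a single factor and a difference in the p53S18P epitope between conditions cannot be told apart with 1 library per group.

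The 83 sites lower after adriamycin with the p53S18P antibody crowded in 1 region: 18 of them lay in 13:21000001-24000000, where 41 sites were called in the untreated p53S18P library. Of 10000 random draws of 83 sites from that library's sites, 0 had as many in a window of 3 Mb, and the highest draw had 5. The draws ignore how the 467 sites called in that library alone are placed. Of those, 28 lay in the region, and 17 of the 18 lowered sites were among them. The draws therefore cannot tell crowding of lowered sites from crowding of sites called in that library alone. Loss of reads over the whole region is argued against by the reads outside sites, whose treated over untreated ratio was 0.890 there. Fragments read from both ends are argued against as the whole source, which would need at least 50% of the reads in pairs. The 261 minus strand reads at the 18 sites in the untreated p53S18P library formed 256 pairs with plus strand reads 1 fragment length away. At distances 30 bp shorter and longer they formed 237 and 196. The excess of pairs equals 15.1% of the reads (95% interval 0.802% to 29.5% from counting, 7.89% to 23.5% over 10000 resamplings of the sites). A read can be in more than 1 pair, so this counts pairs and not reads. The upper counting limit did not fall under the 25% set beforehand as the limit against this explanation, and the verdict rests on the 50%, chosen to decide it after the 15.1% was seen. A smaller part of the reads may be such pairs. What lowers these sites stays open.

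A further pattern was that 32332 of the 78339 treated p53 sites (41.3%) had no p53S18P site. Absence of p53S18P reads is argued against: the median log2 enrichment of the treated p53S18P library at sites called with p53 and not p53S18P was 1.31, against -0.13 at 30278 positions 5 kb away. Against the untreated input, which took no part in calling them, summed p53S18P reads were 2.37-fold at these sites and 0.867-fold at the moved positions. With both libraries thinned to 8773552 reads, 28.9% of 55951 p53 sites had no site among 55763 p53S18P sites. The next test was set out when this share was known. Depth and chance misses near the threshold cannot be told apart from a real difference, since 2 parts of the treated p53 library, split at random, missed 27.2% of each other's sites in one direction and 26.3% in the other. The share of 10% asked of depth was thus out of reach.

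Mitochondrial reads, outside the comparisons, made up 0.115% of the untreated p53S18P library and 0.108% of its input (Fisher's exact test, odds ratio 1.06, p = 3.02e-08). In untreated p53 the share was 0.107% (Fisher's exact test, odds ratio 0.99, p = 0.42). In the treated ChIP libraries the shares were 0.0660% with p53 and 0.0648% with p53S18P, against 0.0922% in the treated input. These differences were larger: the odds ratio was 0.715 with p53 (Fisher's exact test, p = 1.06e-174) and 0.702 with p53S18P (Fisher's exact test, p = 6.74e-127).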

How the results depend on the processing

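The background per 100 kb and the plus strand reads were chosen after seeing the data. Site counts that changed by more than 1.5 times and log2 values that changed direction are given here, and the cause was not tested unless stated. Site counts at a q of 1e-05 were 10916 (untreated) and 47687 (treated) with p53 and 5545 and 34331 with p53S18P. Under the other 8 alternatives they stayed within 1.5 times: treated p53 counts ran from 55951 (thinned) to 95805. Plus strand reads, which hold fewer counts by construction, gave 19524 higher and 27 lower sites with p53 and 37073 and 14 with p53S18P. Lowered p53 sites numbered 116 within 500 bp of the summit and 72 after thinning. Lowered p53S18P sites numbered 244 with total reads. They numbered 135 when p was adjusted over only those merged sites that were called with that antibody. With the median site set to no change, by construction, higher and lower sites numbered 874 and 1639 with p53 and 1421 and 1410 with p53S18P.

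That scaling takes 1.50 (p53) or 2.56 (p53S18P) from every log2 value, so the values it turns at strong sites follow by construction. With p53 they were -0.82 at 3:61166751, -1.21 at 3:104257601, -0.013 at 15:73076351, -1.30 at 12:111962801, -0.67 at 10:90880651, -0.96 at 10:117481751, -0.94 at 17:56847801, -1.02 at 5:22725051, -0.52 at 3:52406851, -1.11 at 4:48834501 and -1.30 at 7:139920601. With p53S18P they were -0.68 at 3:104257601, -0.21 at 15:73076351, -0.90 at 12:111962801, -0.97 at 8:13139501, -1.29 at 10:90880651, -0.51 at 17:56847801, -1.29 at 5:22725051, -0.59 at 4:48834501 and -0.15 at 7:139920601. With total reads p53 values were -0.019 at 12:111962801 and -0.017 at 7:139920601, with all reads kept 0.13 at 8:13139501, and with background per 100 kb -0.17 at 7:139920601. Input correction moved the median log2 fold change to 2.01 with p53 and 3.62 with p53S18P. Of 171 p53 values at named sites 147 kept direction and side of the threshold, and of 189 p53S18P values 172 did. Overlaps of site lists and the spread of the inputs stayed within 1.5 times. Alternatives for gene lists and the motif were not run. No paired analysis was possible because each group has 1 library and the groups share 1 replicate number.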

Other observations

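Reads on opposite strands paired at 1 sharp distance in the inputs. At the fragment length the number of such pairs was 3.23 times that at distances 20 bp away in the untreated input and 1.77 times in the treated input, against 1.10 to 1.34 in the ChIP libraries.

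Read density outside sites varied along the autosomes by different amounts in the libraries. Over 23459 bins of 100 kb, the standard deviation of log2 reads was 0.73 in the treated and 0.36 in the untreated p53S18P library, 0.55 and 0.48 in the p53 libraries, and 0.42 and 0.53 in the inputs.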
